A study of Mus musculus with 6 samples.

How the data were processed

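Mouse mesenchymal stem cells from a commercial supplier were subcultured in supplemented medium. Per the labels' protocols the medium received 4 compounds anew 48 h before exposure, namely 1 µM dexamethasone, 1 µM rosiglitazone, 5 µg/ml insulin and 100 µM isobutylmethylxanthine. Cultures were irradiated for 2 h with a continuous-wave gas laser at a wavelength of 118.8 µm. Total RNA (200 ng) was amplified with an oligo-dT primer into biotin-labelled cRNA and hybridised to Affymetrix arrays.

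The deposited values are log2 expression values per probe set, 1 column per sample, made by the authors with RMA, which corrects background, brings all arrays to 1 distribution by quantile normalization and summarises the probes of a probe set. Per the submitters' processing notes RMA, the affy package and limma were used, and their versions are not given in the sources used here. No label states the log base. The range of the values, 1.73 to 14.53, is that of RMA log2 values, and they were taken as such. They are rounded to 2 decimals. Quantile normalization gives every array the same distribution, so a change common to all transcripts cannot be seen, and RMA tends to understate the changes of dim probe sets. Detection calls, scanner images and hybridization dates were not used here, so that no probe set is called absent and no array batch was tested.

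The table holds 45101 probe sets, of which 64 are the array's control probe sets and 45037 were tested, with no filter on dim ones. Gene symbols came from the platform annotation given for these arrays. It names 1 symbol for 34945 tested probe sets, several for 932 and none for 9160, and 34741 were matched through their Entrez identifiers to a current gene table, with 0 symbols changed. For tests per gene the probe set with the highest mean over the 6 arrays stood for each of 18193 genes. Probe sets with several symbols or none stayed out of the tests per gene. Among the 9160 unnamed probe sets limma with Benjamini-Hochberg called 0, with 478 at an unadjusted p under 0.05, and among the 932 with several symbols it called 0, with 23.

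The main test was limma (version 3.58.1 in R 4.3.3), lmFit and eBayes with default settings, irradiated minus control with the experiment number as a block, and Benjamini-Hochberg adjusted p under 0.05. The pairing comes from the series' design text, which sets each irradiated culture against a control of the same experiment placed beside it. Deviations of same-numbered arrays from their group means correlated across probe sets at 0.087, -0.065 and -0.029 in experiments 1 to 3, and only in experiment 1 did both arrays deviate most with their own number. The fit leaves 2 residual degrees of freedom, to which eBayes added 5.32 for probe sets and 4.66 for genes. Confidence intervals are the moderated ones at 95%.

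Gene lists were written from textbook knowledge and fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They cover adipogenesis, mesenchymal stromal, matrix, osteoblast and chondrocyte genes, heat shock, cold-inducible, immediate early, unfolded protein, p53, NRF2, NF-kB, interferon, hypoxia, dexamethasone, cyclic AMP, calcium, actin, clock, cell cycle, histone, cholesterol, respiratory, ribosomal and housekeeping genes, and markers of 7 other cell types. Of 700 entries 622 were measured, and the cold-inducible genes Rbm3 and Uba1 had no probe set with 1 symbol. limma's camera was run with a preset correlation of 0.01 and again with an estimated one, and fry as a rotation test, on lists of at least 5 measured genes, with Benjamini-Hochberg adjustment over the 31 lists. The text names the 8 genes per direction with the smallest unadjusted p among those at or above the median level and of 1 sign in all 3 experiments, because no gene passed (up to 12 per direction would have been named otherwise). It also names up to 4 members per list with the largest change, and Pparg, Fabp4, Adipoq, Slc2a4, Lpl, Hsph1, Hsp90aa1, Hspa1b and Cirbp in any case.

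The scripts were tested on simulated data with the levels and spreads of these arrays, independent errors for each gene and 50 genes changed per fold size in 20 runs. Fold sizes of 1.25, 1.5, 2 and 3 were planted together in each run, which eases the Benjamini-Hochberg threshold. Recovery may be lower where few genes change. In the test per gene limma recovered 47.3% of genes at 1.5-fold, 94.7% at 2-fold and 99.4% at 3-fold, with 5.61% false calls. For probe sets the shares at these folds were 10.2, 90.2 and 98.2%, with 5.20% false calls. camera called the adipogenesis list as higher in 100% of runs when it was shifted upwards by 0.1 log2 units and in 0% when it was not. Calls of this list as lower were not counted. The simulated genes were independent, so the camera figures do not cover genes that vary together.

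RNA quality was read from the 3' and 5' control probe sets of actin and Gapdh. Alternatives were a fit without the block or with a random block, filters on the mean level, median centring, a second quantile normalization, a mean-variance trend with robust variances, array weights, each experiment left out, an ordinary paired test, a looser threshold, other rules for probe sets of 1 gene, and other list tests. A scaling to the Bacillus control probe sets was added after seeing the data.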

Results

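Gene expression was measured in mouse mesenchymal stem cells, multipotent cells that can form fat, bone and cartilage, growing in dishes under a mixture of rosiglitazone, insulin, isobutylmethylxanthine and dexamethasone, compounds that are commonly used to drive such cells towards fat cells. In each of 3 independent experiments 1 culture was exposed for 2 h to a terahertz laser, which emits far-infrared light, at 2.52 THz. Its control stood beside it at 26 to 27 °C, and RNA was taken as soon as the exposure ended. Each culture was read on 1 Affymetrix mouse array, which gave 6 arrays, 3 per group. The array medians lay between 5.01 and 5.04 on the log2 scale. An array has no read depth, and the number of arrays limits the precision of what follows. The design asks which transcripts differ between an irradiated culture and its own control.

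Genes of fat cells were bright in both groups. Fabp4, the fatty acid binding protein of fat cells, had a mean level of 14.36, Adipoq, which encodes the hormone adiponectin, 13.71 and Lpl, lipoprotein lipase, 13.68, where the median gene lay at 6.46. Of 37 measured adipogenesis genes 34 were at or above that median, as were 20 of 21 heat shock genes, and no culture without the mixture was compared. Levels of different probe sets depend on the probes as well as on the RNA, so these values place a gene on the array's scale and are no ratio between genes.

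No gene passed the test for a difference between irradiated and control cultures. limma with the experiment as a block called 0 of 45037 probe sets and 0 of 18193 genes after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.995 in both. At an unadjusted p under 0.05 it gave 1696 probe sets, 906 higher and 790 lower, where 2252 would be reached by chance alone, and 603 genes, 259 higher and 344 lower. limma without the block also called 0 and 0, with 1841 probe sets and 649 genes at an unadjusted p under 0.05. An ordinary paired test without moderation called 12 probe sets and 8 genes, each with exactly the same difference in all 3 experiments after rounding to 2 decimals, and with changes of at most 0.17 log2 units. The median gene differed by -0.01 log2 units and the SD over genes was 0.11.

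For nearly all genes at or above the median level the 95% confidence interval lay within 2-fold. Over the 9099 genes at or above the median level, the 95% confidence interval of the irradiated-minus-control difference reached 0.20 log2 units, or 1.15-fold, to either side of the estimate (median over genes). It lay within 2-fold in either direction for 9091 of them (99.9%) and within 1.5-fold for 9001 (98.9%). These intervals are per gene, with no adjustment for the number of genes, and they bound changes in the RMA values. Of the 9094 genes below the median level 9088 had an interval within 2-fold too, although RMA tends to understate the changes of dim probe sets. In simulated data of the same size limma called 94.7% of genes changed by 2-fold and 47.3% of those changed by 1.5-fold. Changes below 1.5-fold would therefore mostly have been missed. Genes of all fold sizes were changed in the same runs, and these shares may be lower where few genes change.

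Among genes at or above the median level that kept their sign in all 3 experiments, those with the smallest unadjusted p differed by at most 0.45 log2 units upwards and -0.49 downwards. On the higher side were Akr1c18, a hydroxysteroid dehydrogenase (0.45 log2 units, SE 0.13, n = 3 pairs), Edil3, a secreted integrin-binding protein (0.30), Map4k5, a kinase (0.30), Pappa, a protease that cuts insulin-like growth factor binding proteins (0.28), Crk, a signalling adaptor (0.25), Zfp180 (0.25), Sat1, which acetylates polyamines (0.24), and the centromere gene Cenpc1 (0.24). The lower side held the chemokine Ccl12 (-0.49, SE 0.13), A630072M18Rik (-0.36), Slc16a6 of the monocarboxylate transporter family (-0.35), the interferon-induced Gbp7 (-0.35), the mitochondrial carrier Slc25a44 (-0.31), Ydjc (-0.31), Numbl (-0.29) and Pld4 (-0.27). All 16 had an adjusted p of 0.995 in limma with Benjamini-Hochberg, and none passed. All 5 probe sets of Crk and all 3 of Map4k5 had a mean above 0, whereas other probe sets of Edil3 ranged from -0.40 to 0.10 and those of Slc25a44 were -0.11 and -0.0033.

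**Figure D1:**
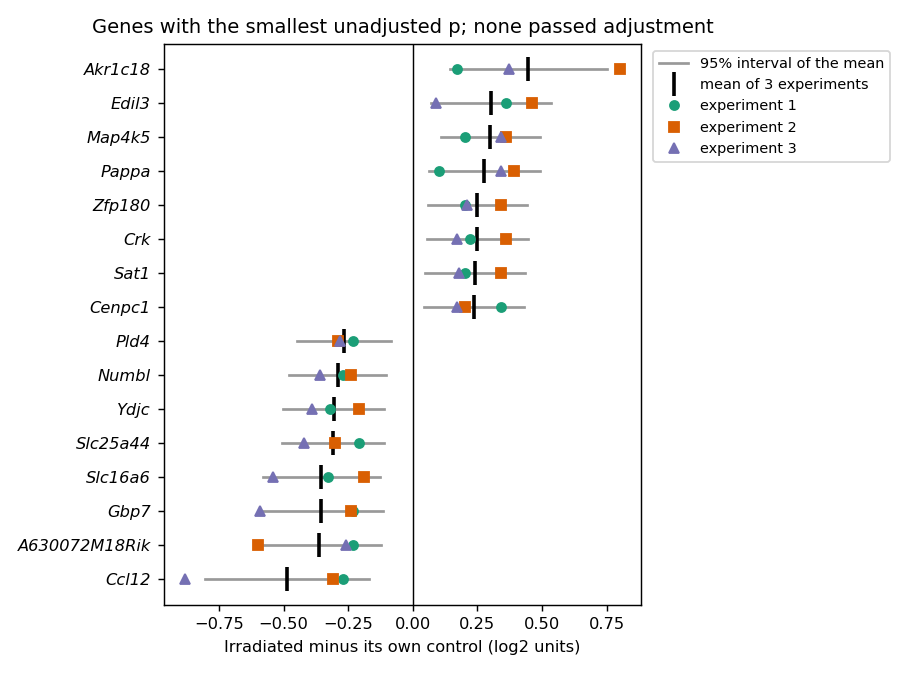
Irradiated minus control difference (log2 units, horizontal axis) of 16 genes, the 8 per direction with the smallest unadjusted p among those at or above the median level and of 1 sign in all experiments. Coloured symbols are the 3 experiments, black ticks their mean and grey lines its 95% confidence interval from limma; the means run from 0.45 for Akr1c18 to -0.49 for Ccl12, and no gene passed Benjamini-Hochberg adjustment.

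Of 32 gene lists fixed beforehand, no list had a member that passed, either over all 18193 genes or adjusted over the list alone. The lists held 622 measured entries, which were 603 different genes. limma's camera with its preset correlation called 3 of the 31 lists large enough to test, and 8 at an unadjusted p under 0.05. With the correlation estimated from the data it called 0 lists, and 0 had an unadjusted p under 0.05. That estimate rests on 2 residual degrees of freedom. It ran from -0.065 for the blood cell markers to 0.62 for adipogenesis, with 0.53 for the cell cycle and 0.51 for the actin list. Where genes vary together, p values at the preset correlation of 0.01 do not measure the spread between experiments. With the estimated correlation, Benjamini-Hochberg adjustment gave all tested lists but the ribosomal one the same adjusted p of 0.935. That does not set 1 list apart from another. The smallest unadjusted p in this camera test was 0.0786, for the osteoblast list. fry, which asks whether a list's genes move one way on balance, also called 0, with 2 lists at an unadjusted p under 0.05, the circadian clock and the blood cell markers.

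The adipogenesis list was lower on average, by a difference that came from 1 experiment. Its 37 measured genes had a mean of -0.11 ± 0.30 log2 units (SD, n = 3 experiments), and 31 of them were below 0. camera gave a Benjamini-Hochberg adjusted p of 0.0264 in limma, and the adjusted p = 0.935 with an estimated correlation. The mean was -0.45 in experiment 2, where 34 genes were lower, against 0.035 in experiment 1 and 0.086 in experiment 3. Without experiment 2 the list stood at 0.060, on the other side of 0, with an adjusted p of 0.0856 in limma's camera after Benjamini-Hochberg adjustment. Lipe, hormone-sensitive lipase, differed by -0.42 (SE 0.22; -1.17 in experiment 2), Adig, or adipogenin, by -0.41 (SE 0.17), the glycerol channel Aqp7 by -0.37 (SE 0.20) and Pnpla2, adipose triglyceride lipase, by -0.27 (SE 0.17). Pparg, the regulator of fat-cell formation that rosiglitazone activates, was at -0.19 (SE 0.13) and the insulin-responsive glucose transporter Slc2a4 at -0.19 (SE 0.14), while Adipoq (-0.043), Fabp4 (-0.023) and Lpl (-0.0067) lay close to 0. Dimmer probe sets of Fabp4 stood at -0.17 (level 9.325) and -0.29 (level 8.45), each at -0.67 in experiment 2, and another at 0.0033 (level 13.12).

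Stromal and bone-forming genes were slightly higher on average. The mesenchymal stromal list had a mean of 0.072 ± 0.035 log2 units (SD, n = 3), with 15 of 19 genes above 0 and a mean above 0 in every experiment, and the osteoblast list 0.13 ± 0.14, with 10 of 11 genes above 0 and means of -0.0045, 0.28 and 0.12 in experiments 1 to 3. Of the osteoblast genes 4 of 11 reached the median gene level, against 16 of 19 stromal genes. Both had a Benjamini-Hochberg adjusted p of 0.0258 in limma's camera, and an adjusted p = 0.935 with an estimated correlation. Without experiment 2 the stromal mean was 0.053 (adjusted p 0.295) and the osteoblast mean 0.059 (adjusted p 0.534) in the same limma test with Benjamini-Hochberg, and without experiment 1 the osteoblast mean was 0.20 (adjusted p 0.00643). No list was called in a fit without the block, where the lowest adjusted p from limma's camera was 0.0630 after Benjamini-Hochberg. S100a4 differed by 0.23 (SE 0.13), the surface enzyme Nt5e by 0.21 (SE 0.081) and the integrin Itgb1 by 0.18 (SE 0.087), and in the osteoblast list Ibsp, bone sialoprotein, by 0.56 (SE 0.21; -0.16, 0.98 and 0.85 in the 3 experiments) and the transcription factor Sp7 by 0.19 (SE 0.078). The matrix list (0.068 ± 0.14; 18 of 25 genes above 0) and the list of actin, SRF and YAP targets (0.078 ± 0.19; 16 of 23) were not called, at Benjamini-Hochberg adjusted p values of 0.0751 and 0.0597 in limma's camera. In both, experiment 1 had a mean below 0 and experiments 2 and 3 a mean above 0. The matrix list was called in 6 and the actin list in 7 of 15 other settings. Without experiment 1 the matrix list stood at 0.15 and the actin list at 0.18. Both were then called, at Benjamini-Hochberg adjusted p values of 0.000570 and 6.39e-05 in limma's camera, on 2 pairs and with the preset correlation. Without experiment 2 they stood at 0.029 and -0.015 (adjusted p 0.738 for both in limma's camera with Benjamini-Hochberg), and over all 3 experiments both had an adjusted p = 0.935 with an estimated correlation. Postn, periostin, was at -0.52, 0.83 and 1.05 in the 3 experiments, and the smooth muscle gene Tagln at -0.30, 0.69 and 0.64. The chondrocyte list stood at -0.022 ± 0.092.

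**Figure D2:**
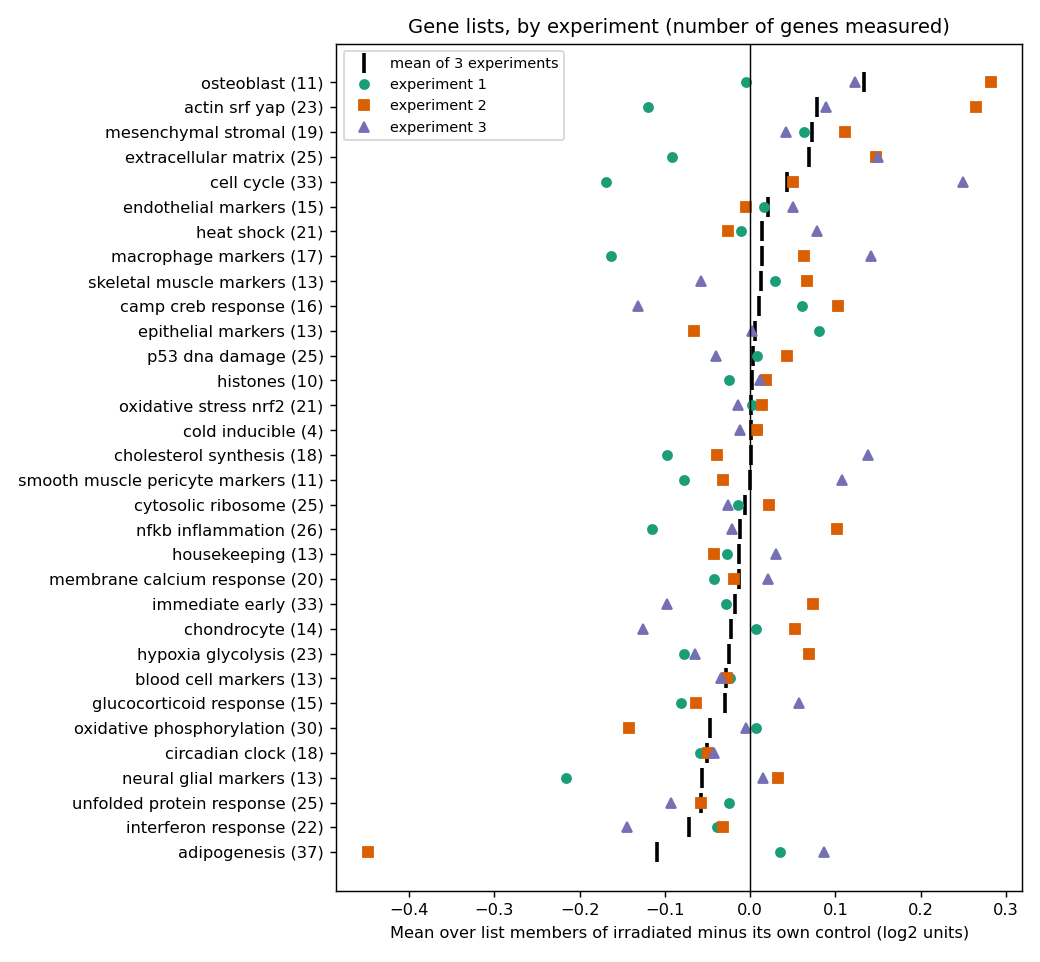
Mean over the members of each gene list of the irradiated minus control difference (log2 units, horizontal axis), with the number of genes measured in parentheses. Coloured symbols are the 3 experiments and black ticks their mean, which runs from 0.13 for the osteoblast list to -0.11 for adipogenesis, where experiment 2 stands alone at -0.45.

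The heat shock list was not called. Its 21 measured genes, each read by 1 probe set, most of them chaperones and their helpers, had a mean of 0.014 ± 0.056 log2 units (SD, n = 3), and the 95% intervals of all 21 lay between -0.38 and 0.44. Hsp90aa1 differed by 0.063 (SE 0.079) and Hsph1 by 0.023 (SE 0.081). The 4 other probe sets of Hsp90aa1 were above 0 too: 0.19 (level 11.35), 0.14 (level 10.54) and, at levels of 4.57 and 3.20, 0.050 and 0.29, the last with 0.34, 0.38 and 0.16 in the 3 experiments (unadjusted p 0.0145 in limma). Hspa1a (0.13, SE 0.11) and Hspa1b (0.073, SE 0.078), the classical heat-inducible genes, are nearly identical, and a probe set of either can also read the other. Both other probe sets of Hspa1b were higher, at 0.14 (SE 0.099) and 0.29 (SE 0.099; 0.18, 0.21 and 0.48 in the 3 experiments). Bag3, a co-chaperone, was at -0.19 (SE 0.080). All 4 measured cold-inducible genes were near 0, Cirbp at -0.057 (SE 0.11) and Cdk4 at 0.043 (SE 0.083), and 4 genes were too few for a list test.

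Other stress and signalling lists stayed within 0.08 log2 units of 0. The immediate early genes, which respond to stimuli within minutes to hours, averaged -0.017 ± 0.086 (SD, n = 3), with 12 of 33 above 0. Among them Egr3 differed by 0.26 (SE 0.091) and Zfp36, which destabilises inflammatory transcripts, by -0.20 (SE 0.078). The unfolded protein response list averaged -0.058 ± 0.034, with 19 of 25 genes below 0, including Trib3 (-0.36, SE 0.14), Chac1 (-0.28, SE 0.10) and Asns (-0.21, SE 0.11). In experiments 1 to 3 Trib3 stood at -0.080, -0.19 and -0.80, Chac1 at -0.10, -0.23 and -0.52 and Asns at -0.010, -0.14 and -0.48, each furthest from 0 in experiment 3. The interferon list averaged -0.072 ± 0.063, with 18 of 22 genes below 0, including Usp18 (-0.31, SE 0.12; level 3.91) and Gbp2 (-0.18, SE 0.11; level 8.285). Of its 22 genes 9 reached the median gene level. Benjamini-Hochberg adjusted p values of these 3 lists in limma's camera were 0.832, 0.181 and 0.0597, and 0.935 for each with an estimated correlation. The interferon list was called in 9 of 15 other settings, among them without experiment 1 at an adjusted p of 0.0275 in limma's camera with Benjamini-Hochberg. Without experiment 3 its mean was -0.036, at an adjusted p of 0.572 in the same limma test with Benjamini-Hochberg, and the control of experiment 3 was the highest of the 6 arrays, at 0.11 above their mean where the others lay between -0.037 and 0.0049. That array also stood apart in the difference between the 3' and 5' probe sets of actin, at 0.68 against 0.50 to 0.57, and of Gapdh. DNA damage genes of the p53 pathway stood at 0.0037 ± 0.041, with Cdkn1a, the p21 cell cycle inhibitor, at -0.11 (SE 0.085), and oxidative stress genes controlled by NRF2 at 0.00095 ± 0.014. The NF-kB list stood at -0.012 ± 0.11, with Il6 at -0.31 (SE 0.10). Hypoxia and glycolysis genes averaged -0.025 ± 0.081 and genes of membrane and calcium signalling -0.014 ± 0.032, with Stim1, the calcium sensor of the endoplasmic reticulum, at -0.21 (SE 0.079). The other probe set of Stim1 had a similar level (7.53 against 7.88) and stood at 0.067, with 0.04, 0.06 and 0.1 in the 3 experiments. Genes that respond to glucocorticoids such as dexamethasone and to cyclic AMP, which isobutylmethylxanthine raises, averaged -0.029 ± 0.075 and 0.011 ± 0.13.

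Growth and housekeeping lists differed little. Cell cycle genes averaged 0.044 ± 0.21 (SD, n = 3), with 27 of 33 above 0, and split by experiment at -0.17, 0.051 and 0.25. The list was called in 4 of 15 other settings, among them at or above the median level (Benjamini-Hochberg adjusted p 0.0310 in limma's camera). Without experiment 1 the list mean was 0.15, and limma's camera called it at a Benjamini-Hochberg adjusted p of 9.30e-06. That p rests on 2 pairs and the preset correlation of 0.01, where the estimated one over all 3 experiments was 0.53. Without experiment 3 the mean was -0.059, and over all 3 experiments limma's camera gave a Benjamini-Hochberg adjusted p = 0.935 with an estimated correlation. Cdk1 was at 0.21 (SE 0.13) and Mki67, a marker of dividing cells, at 0.14 (SE 0.16). The list averages were -0.047 ± 0.083 for oxidative phosphorylation, -0.0060 ± 0.025 for cytosolic ribosomal proteins, 0.00037 ± 0.12 for cholesterol synthesis, 0.0017 ± 0.023 for histones, a list of core histones that also held the linker histones H1f2 and H1f4, and -0.013 ± 0.038 for housekeeping genes. Of these the respiratory list was called in 2 of 15 other settings, among them without experiment 1, at -0.074 and a Benjamini-Hochberg adjusted p of 0.00643 in limma's camera. Its mean was -0.14 in experiment 2 and 0.0010 without that experiment, and its adjusted p = 0.935 with an estimated correlation in limma's camera over all 3 experiments, after Benjamini-Hochberg. The 18 circadian clock genes averaged -0.050 ± 0.0081, with Rora at -0.21 (SE 0.076) and Nr1d1 at -0.13 (SE 0.077), at a Benjamini-Hochberg adjusted p of 0.220 in limma's camera and 0.227 in fry. In 4 lists, cyclic AMP, cholesterol synthesis, histones and epithelial markers, the mean was above 0 and the median below it.

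In the main fit over all 3 experiments, no list of markers of other cell types was called in limma's camera. All 17 measured macrophage markers were at or above the median gene level in these cultures, and the list differed by 0.014 ± 0.16 log2 units (SD, n = 3) at -0.16, 0.063 and 0.14 in the 3 experiments. Experiment 1 was the lowest of the 3 in this list and also in the actin, matrix and cell cycle lists. Without it the macrophage list stood at 0.10, with a Benjamini-Hochberg adjusted p of 0.0192 in limma's camera. Without experiment 2 or 3 it stood at -0.011 or -0.050, and over all 3 experiments limma's camera gave a Benjamini-Hochberg adjusted p = 0.935 with an estimated correlation. Cd14 was at 0.21 (SE 0.18) and C1qb at 0.077 (SE 0.12). Of the markers of other types few reached the median gene level: 1 of 15 for endothelium, 0 of 13 for skeletal muscle, 1 of 13 for epithelium, 1 of 13 for blood cells, 2 of 13 for neural cells and 3 of 11 for smooth muscle and pericytes. Their differences were 0.021 ± 0.028, 0.013 ± 0.064, 0.0054 ± 0.073, -0.028 ± 0.0055, -0.056 ± 0.14 and -0.00061 ± 0.096 in that order.

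Measures of RNA quality differed between the groups by less than the spread between experiments. The difference between the 3' and 5' probe sets of actin changed from control to irradiated by -0.060 ± 0.11 log2 units (SD, n = 3 pairs; exact sign-flip permutation test, two-sided, p = 0.75), and that of Gapdh by -0.077 ± 0.12 (exact p = 0.25, the smallest that 3 pairs can give). The control of experiment 3 stood apart, with a Gapdh difference of 0.11 where the other 5 arrays lay between -0.10 and -0.08. Without experiment 3 the differences were 0 for actin and -0.010 for Gapdh.

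An irradiated culture lay about as far from its own control as cultures of a single group lay from each other. The SD over probe sets of the difference between 2 arrays was 0.21 for an irradiated array and its own control (mean of 3 pairs), 0.22 for pairs of controls (3 pairs) and 0.20 for pairs of irradiated arrays (3 pairs). Irradiation took 18.02% of the sum of squares, the experiment 41.1% and the remainder 40.9%, where equal noise on all arrays would give 20, 40 and 40%. The differences of the 3 experiments did not line up across probe sets, with correlations of -0.052, -0.064 and -0.0092. Of 18193 genes 3828 (21.0%) had the same sign in all 3. Among genes with no difference of exactly 0 the share was 22.9%, where chance gives 25%.

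**Figure D3:**
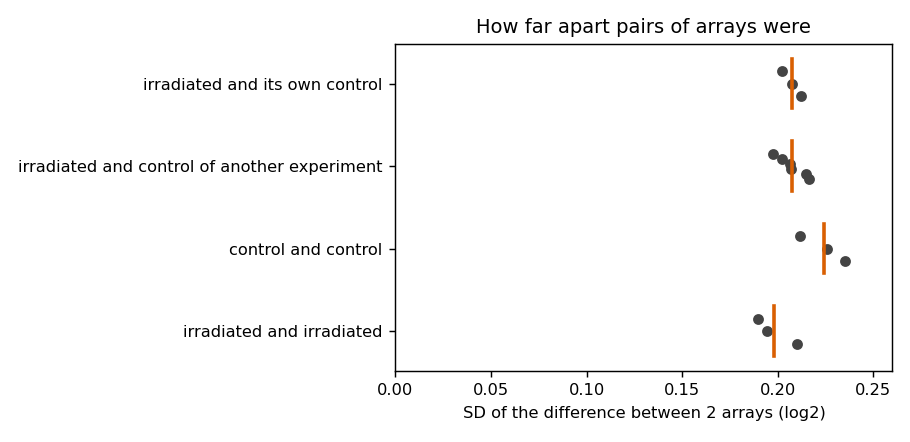
SD over probe sets of the difference between 2 arrays (log2 units, horizontal axis) for each of the 15 pairs of arrays, by kind of pair. Points are pairs and orange bars the mean of each kind, 0.21 for an irradiated array and its own control and 0.22 for 2 controls.

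**Figure D4:**
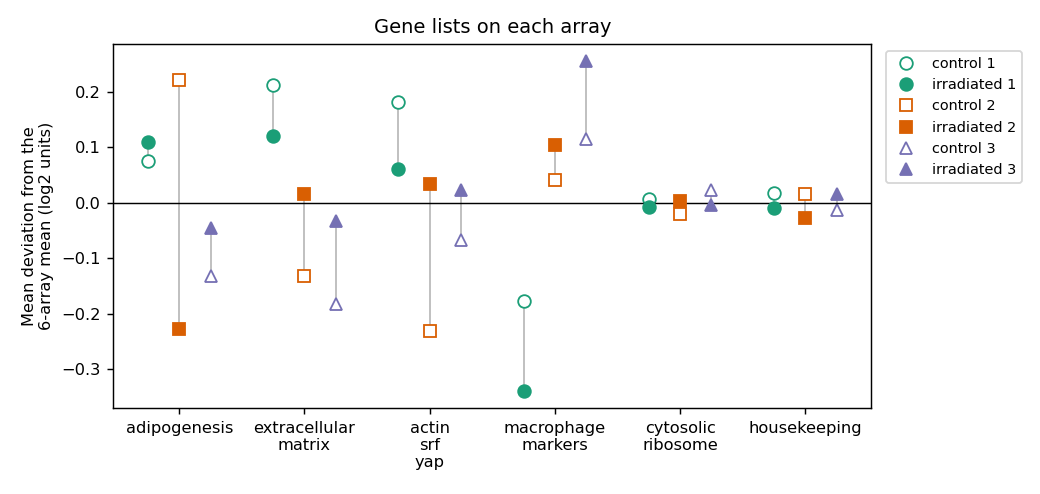
Mean deviation of 6 gene lists from their average over the 6 arrays (log2 units, vertical axis) on each array. Open symbols are controls, filled symbols irradiated arrays and grey lines join the arrays of 1 experiment; the control and irradiated arrays of experiment 2 lie at 0.22 and -0.23 for adipogenesis, and both arrays of experiment 1 are lowest for macrophage markers.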

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

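The calls of 0 probe sets and 0 genes held in limma under every setting fixed beforehand except the ordinary paired test, which called 12 and 8 because rounding left 3 equal differences. Unadjusted p values under 0.05 ran from 522 of 17474 probe sets, at a level of at least 6, to 1952 of 45037. Their balance turned from 906 higher and 790 lower in the main fit to 750 and 933 after median centring. In the ordinary paired test it was 864 and 1088. A fit with no replicate block called 0 probe sets, 0 genes and 0 lists where the block gave 3 lists, and the pairing changed no other call. The number of lists called moved most: 0 with a random block, 7 at or above the median level, 7 at a level of at least 6, 5 after median centring, 4 after a second quantile normalization, 7 with a trend and robust variances, 5 with array weights, 6 with the mean of all probe sets of a gene, 0 with an estimated correlation, 0 with fry in place of camera, and 0 to 9 when an experiment was left out (9 without experiment 1, 0 without experiment 2). The adipogenesis mean ran from -0.21 to 0.060 with an experiment left out and reversed only without experiment 2. The causes of these list changes were not tested. The adjusted p of the adipogenesis list ran from 1.21e-05 to 0.981 over 15 alternatives, and 10 of them called it. The median distance from estimate to limit of the 95% interval was 0.184 without the block, 0.182 with a trend and 0.265 to 0.269 with 2 experiments, where fewer arrays are the cause, and 99.3 to 99.7% of genes then lay within 2-fold. With 2 experiments irradiation took 29.2 to 35.0% of the sum of squares, the experiment 29.2 to 37.5% and the remainder 33.2 to 35.7%, where equal noise would give 3 equal shares, and the mean correlation of differences was -0.064 to -0.0092. At a level of at least 6 the remainder took 42.4% and that correlation was -0.076. Scaling the arrays to equal Bacillus poly-A controls, chosen after seeing the data, called 12 probe sets, 3 genes (all higher) and 6 lists. It adds 1 amount to every gene of an array and so moved the median difference of all genes to 0.28. The cause of the added list calls was not tested. Ibsp was then called, at 0.85 against 0.56 as deposited. For 152 named genes under 8 settings, 104 of 1216 values changed sign, 64 of them under this scaling and 3, 21 and 16 without experiments 1, 2 and 3. No named gene was called as deposited, so none could lose a call. Signal over background was not used here, so no limit for weak probe sets can be stated.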

Other observations

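The tests on the adipogenesis list, the control probe sets and the macrophage genes were chosen after the results were seen, and the counts of other splits were planned. Macrophage genes were among the brighter transcripts of these cultures. Csf1r, the receptor of the macrophage growth factor, had a mean level of 12.78, Mrc1, the mannose receptor, 12.31, Cd68 12.28 and the complement gene C1qa 11.89, on all 6 arrays and in both groups. The acute-phase gene Saa3 stood at 12.72. A few genes outside the lists had the largest differences, and they were picked after their values were seen because they exceeded 1.5-fold, with no gene passing limma's Benjamini-Hochberg adjustment. Car3, a carbonic anhydrase, differed by -0.91 (0.040, -2.23 and -0.53 in experiments 1 to 3), the fatty acid receptor Ffar4 by -0.75 (-0.47, -1.33 and -0.45), the lactate receptor Hcar1 by -0.71 (-0.35, -1.34 and -0.43) and G0s2, an inhibitor of lipolysis, by -0.59 (0.13, -1.10 and -0.79). Ptar1 differed by -0.61 (-0.37, -0.85 and -0.61), and the organic anion transporter Slco4a1 by 1.06, from 1 experiment (-0.030, 0.28 and 2.93). Of these 6 genes only Car3 and G0s2 lay at or above the median gene level, and Car3 owed most of its difference to experiment 2.

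Genes of fat cells were lower in the irradiated culture of experiment 2, where 34 of 37 adipogenesis genes lay below the control. In the same experiment the osteoblast list stood at 0.28, the actin list at 0.26, the matrix list at 0.15, oxidative phosphorylation at -0.14 and the poly-A controls at -0.52, their largest difference. A drop of that size in every irradiated culture is argued against by experiments 1 and 3, whose list means were above 0 and averaged 0.060, and a smaller common drop is not excluded. Differences in adipogenic state between dishes stay open. Against the average of all arrays, the control of experiment 2 was the highest array, at 0.22. Its irradiated culture was the lowest, at -0.23. That average spans all 3 experiments, so it cannot tell which dish of experiment 2 gave the difference of -0.45. The list mean spanned 0.354 log2 units over all controls and 0.336 over all irradiated cultures, each less than the size of that difference. Without experiment 2, the controls of experiments 1 and 3 differed by 0.206. Dishes of different experiments do not give the spread within an experiment. An effect of the irradiation in experiment 2 alone stays open too, since 1 dish per group and experiment cannot separate it from the dish.

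The poly-A control probe sets for Bacillus transcripts were lower on the irradiated arrays, at -0.037, -0.52 and -0.31 in experiments 1 to 3 (mean -0.29 ± 0.24 SD, n = 3, exact p = 0.25, the smallest that 3 pairs can give). Averaged over the experiments, all 24 probe sets for dap, lys, phe and thr lay below 0. In experiment 1 several of them lay above 0, up to 0.18, and they read only these transcripts. The 3 probe sets for trpn, another Bacillus transcript, lay at levels of 2.54 to 3.07 and were not included, at 0.047, -0.083 and 0.23. A dimming common to a whole array is removed by quantile normalization, so the 18 hybridization controls cannot show it. They differed by 0.061 ± 0.15 and were above the poly-A controls in every experiment, so hybridization and poly-A controls did not move together. An uneven amount of added control RNA may be the source and could not be tested further, because the 18S probe sets, which read the cells' own RNA, also differed below 0, at -0.12, -0.26 and -0.67 in experiments 1 to 3 (mean -0.353, 95% interval -1.06 to 0.36, n = 3, exact p = 0.25). The labels do not say that control RNA was added, and an irradiated culture with more messenger RNA per unit of total RNA would give the same sign, which stays untested. Of the 64 control probe sets 0 passed in limma with Benjamini-Hochberg adjustment, and 18 had an unadjusted p under 0.05.

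Macrophage genes were lower on both arrays of experiment 1. All 17 measured markers were lowest there, with a mean difference from experiments 2 and 3 of -0.39 log2 units, and Lyve1, Saa3, Il6, Clec10a, Ccl8 and Mrc1 were among the 7 genes with the smallest p for a difference between experiments. limma called 0 genes for the experiment after Benjamini-Hochberg adjustment (smallest adjusted p 0.0661, for Lyve1), with 994 at an unadjusted p under 0.05. Scaling of whole arrays is removed by quantile normalization, so the housekeeping list would lie near 0 with or without it and cannot test it. That list differed by 0.00654, so it did not share the macrophage difference. A smaller share of macrophage-like cells in experiment 1 and a change of state in the same cells both stay open. In the same comparison the osteoblast list stood at 0.28, the matrix list at 0.25, the actin list at 0.18 and the adipogenesis list at 0.14. The mesenchymal stromal list stood at 0.058 and the NF-kB list at -0.14, and these values do not decide between the explanations. A change of share alone would move all markers by about the same amount, and the SD of 0.177 over markers exceeded that of the housekeeping list (0.059) without reaching the mean difference, while bright probe sets can compress such differences. All 17 markers are at or above the median gene level in these cultures, mesenchymal cells can express some of them, and no label names a sort that would remove macrophages.

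Splits of the 6 arrays that part every pair but mix the groups called more lists than the real one. Among the 4 splits that part every pair, the real one called 0 probe sets, 0 genes and 3 lists, and the highest of the others 0, 0 and 6. These 4 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1696 probe sets, and the highest of the others 2621. Without the block the real split called 0 lists and the other 3 that part every pair 5 each. The 4 splits that set both arrays of experiment 1 against both arrays of another experiment called 7 to 10 lists, and the 2 that set experiment 2 against experiment 3 called 4 and 0.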
